A study of Caenorhabditis elegans with 2 samples.

How the data were processed

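The material was whole *C. elegans* late embryos of strain OP587, in 2 biological replicates of 1 group, per the labels. Chromatin was sheared by sonication and precipitated with an antibody against green fluorescent protein, per the labels' protocols. For each of the genome builds ce10 and ce11 there were 4 region lists: the regions that entered the reproducibility filter (IDR) for replicate 1, for replicate 2 and for both replicates pooled, and the optimal list that the filter kept. The deposited file records say that the lists for single replicates and for the pool were made from alignments together with a control alignment, and that the optimal list came from both replicate lists and the pooled list. The aligner, the peak caller, their settings and the depth of sequencing are not given in the sources used here. The control libraries were not analysed here.

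The deposited signal value of each region is the authors' own value from the peak caller, of unknown scale, and was used to rank and describe regions within a list. The deposited −log10 q-value of each region, also the authors', reached a ceiling of 3.03 in 536 of the 772 optimal regions, so it was not used for ranking. The deposited summit position (an offset from the region start) gave the point used to place each region. The lists hold candidate regions and background, so a region outside the optimal list is not evidence of binding. In ce11 the 772 optimal regions were exactly the 772 pooled regions of highest signal value, and in ce10 the 764 optimal regions were the 764 highest. The comparison of optimal with other pooled regions is thus one of strong with weak signal in 1 list, and anything that raises read coverage raises a region's chance of being optimal. Regions are not independent replicates, and their p-values describe these lists.

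Coordinates of ce11 were used with the matching assembly WBcel235, its Ensembl gene annotation (release 115), its RefSeq sequence and the RefSeq names of tRNA products. The ce10 lists served only for counts and shares per chromosome, and nothing was converted between builds. Positions are 1-based. Each listed region was counted, also where regions overlap or share coordinates and differ in summit. A summit was placed in a promoter if it lay from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene, otherwise in an exon, an intron or intergenic sequence of protein-coding genes. The annotated 5′ end of many worm genes is the site of trans-splicing and not the start of transcription, so distances to it are approximate. A summit was near a noncoding gene if within 300 bp of it. Reads of repeated genes such as tRNA genes cannot always be placed, and how the authors treated them is not given in the sources used here.

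Shares were compared by two-sided Fisher's exact tests with 95% limits of the odds ratio by the normal approximation on its logarithm, shares have 95% Wilson intervals, which cover counting error only, and p-values of a family were adjusted by the Benjamini-Hochberg method. For gene lists, the background was the 7127 protein-coding genes with at least 1 pooled summit in the promoter window, of which 562 had an optimal summit. Of 31 lists fixed before the data were examined, 30 had at least 5 background genes and were tested, and the list of the tagged gene and the strain's rescue marker was too small. Means were compared by two-sided permutation tests with 100000 resamples. Replicate agreement was tested against 1000 circular shifts within chromosomes, one-sided. Sequence windows were 101 bp centred on the summit. Each 6-mer was counted with its reverse complement, as present or absent, against windows matched 3 to 1 on promoter status and on GC in steps of 2 percentage points. Named genes were, by a rule fixed before the data were examined, the 20 protein-coding genes of the strongest promoter regions (21 with ties), the 4 strongest members of each list past the threshold, and *madf-2*. The comparisons of GC by location, of CpG counts, of each noncoding gene and of tRNA genes by chromosome were added after the data were seen. Other named genes were chosen after their values were seen.

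Alternatives fixed in advance were a stricter threshold (the stronger 386 of the optimal regions), the 772 strongest regions of a single replicate, a background of regions present in both replicates, merged overlapping regions, other promoter windows, distances, sequence windows and word lengths, other gene backgrounds, other overlap rules and the ce10 lists. Leaving out regions near tRNA genes, and leaving out the mitochondrial regions of replicate 2, were added after the data were seen. The tests were also tested on simulated data. With nothing planted, 0 of 2080 6-mers were called, and a 6-mer written into 10% of windows ranked 1. Over 20 random draws of genes 1 list was called. The ribosomal protein list, one of the larger lists (73 genes in the main comparison), was called in 13 of 20 draws when drawn 4 times as often. Even a strong enrichment of a larger list can thus be missed. Smaller lists, which were not simulated, give less power. The permutation test of GC gave p under 0.05 in 3 of 100 draws with nothing planted and in 100 of 100 with 2 percentage points added. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.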

Results

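Binding of the *Caenorhabditis elegans* protein MADF-2 to chromatin was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in late embryos. The worms (strain OP587) carried an inserted transgene that expresses MADF-2 with a C-terminal tag of green fluorescent protein and FLAG, and the precipitation used an antibody against the fluorescent protein. The MADF domain is a DNA-binding fold related to the Myb domain. Embryos of both sexes were collected 3 hours after synchronisation by bleaching, as 2 biological replicates of 1 group, so the study holds no treated or mutant group to compare. The question the data address is where in the genome the tagged protein was recovered. Replicate 1 had a list of 30000 candidate regions, replicate 2 had 27350, and the list called on both replicates pooled had 30000. The authors' filter for reproducible regions (IDR, the irreproducible discovery rate) kept 772 of the pooled regions, called optimal regions here, and these were compared with the other 29228 pooled regions. The optimal regions had a median width of 396 bp and a median signal value of 95.2 (range 69.6 to 1036). The signal value is the authors' own value per region and was used to rank regions within a list. Read depth per library is unknown from these lists. All coordinates are in the ce11 genome build.

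The strongest recovery of MADF-2 was at a small set of loci seen in both replicates. The highest signal value, 1036, lay on chromosome X from 9999341 to 10000214, between the divergent genes *grk-1*, which encodes a kinase of G protein-coupled receptors, and *F19C6.2*. Its summit was 732 bp upstream of the 5′ end of *grk-1* and 995 bp upstream of that of *F19C6.2*. The next highest was on chromosome II from 11634051 to 11634631, 689 bp upstream of *din-1* (signal value 904), which encodes a corepressor that binds the nuclear receptor DAF-12. Another strong locus was on chromosome II from 14250026 to 14250672, 330 bp upstream of *hmg-1.1*, an HMG-box chromatin protein (signal value 842). The region upstream of *K12H4.5* on chromosome III, from 8043813 to 8044124, had a signal value of 576. In the 6.31 kb around *hmg-1.1* there were 6 listed optimal regions in 4 separate stretches, as some share or overlap their coordinates and differ in summit, and 3 of the 10 strongest regions of the genome were among them: the region upstream of *hmg-1.1*, a region outside protein-coding genes at 14249520 to 14249918 (signal value 544), whose summit lies in the noncoding RNA gene *Y48B6A.23*, and a region 793 bp upstream of *Y54G11A.2* (signal value 478). A weaker summit at 14250568 lies in the overlapping noncoding RNA genes *Y48B6A.18* and *Y48B6A.21*. The strong summit upstream of *hmg-1.1* is also within 300 bp of these noncoding genes. The region upstream of *Y54G11A.2* overlaps the 3′ end of *hmg-1.1*. Among the 772 strongest regions of replicate 1, 458 (59.3%) overlapped one of the 772 strongest of replicate 2 by at least 1 bp. Shifting the regions of replicate 2 along the chromosomes 1000 times gave a mean of 0.610% and at most 9.20% (one-sided permutation test, p = 0.001, the smallest that the shifts can give). Of the 772 optimal regions, 766 overlapped a region in both replicate lists. The optimal list was made from both replicate lists and the pooled list, so this overlap is not independent evidence of agreement. Of the other pooled regions, 11775 were also present in both replicate lists. Over these 766 regions, which are not independent replicates, the signal values of the 2 replicates had a Spearman rho of 0.522. Over all 12560 regions of replicate 1 that overlapped one of replicate 2, chosen without regard to strength, rho was 0.299. The first rho took the strongest overlapping region of each list, and the second the replicate 2 region of greatest overlap. Some of the 766 regions also share the same replicate values, so these rho values are not directly comparable.

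**Figure D1:**
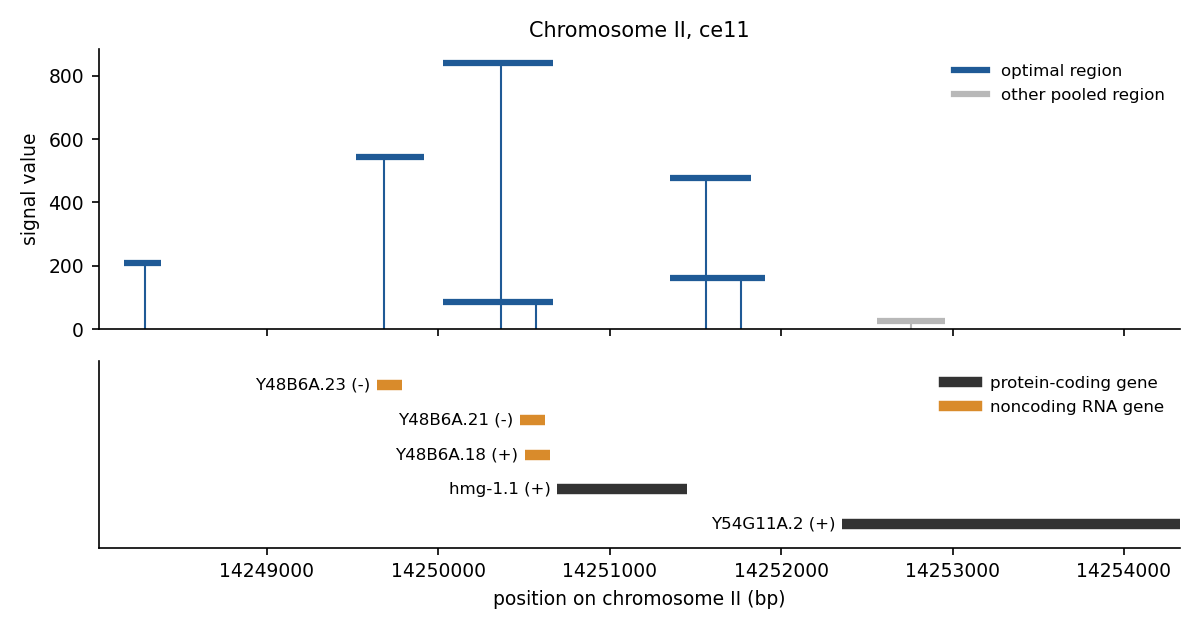
Optimal regions around *hmg-1.1* on chromosome II in ce11. Horizontal bars in the upper panel give the extent (x axis, bp) and signal value (y axis) of each pooled-list region, with a vertical line at its summit, and the lower panel gives the annotated genes with their strand. The region upstream of *hmg-1.1* reaches 842, and the only pooled region outside the optimal list has a signal value of 26.9.

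**Figure D2:**
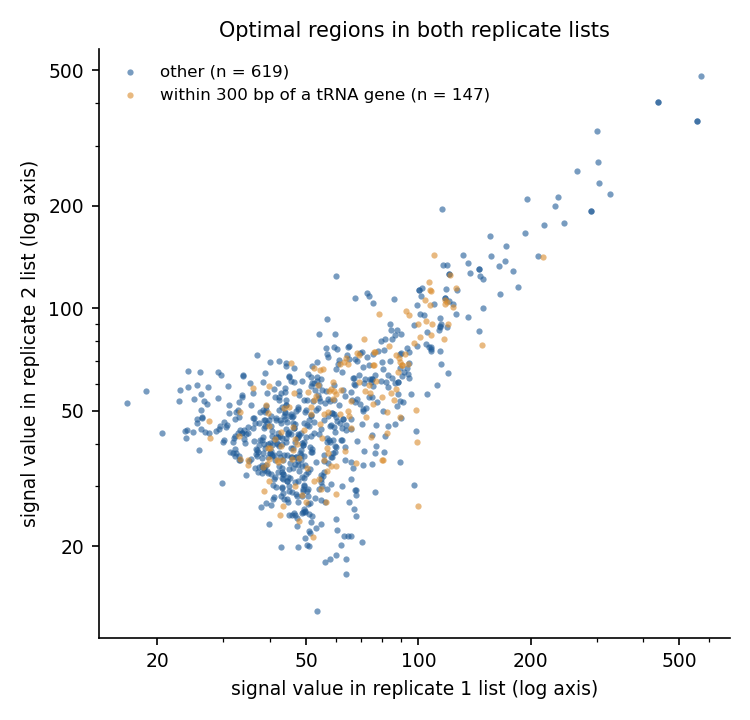
Signal value of the 766 optimal regions found in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both log axes. Each point is 1 region and orange points lie within 300 bp of a tRNA gene. The strongest regions lie high in both lists and the weaker ones scatter widely, with a Spearman rho of 0.522.

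Optimal regions lay in the promoters of protein-coding genes more often than other pooled regions did, and rarely in exons. Of the 772 summits, 409 (53%, 95% Wilson interval 49.5 to 56.5%) were within the window from 1000 bp upstream to 200 bp downstream of an annotated 5′ end, against 23.3% of the other pooled regions (odds ratio 3.70, 95% limits 3.21 to 4.28, adjusted exact p = 2.85e-68). The promoter share ranged from 43.5%, with a window of 500 bp upstream to 100 bp downstream, to 64.9%, with one of 2000 bp upstream to 500 bp downstream. It was 48.6% with the strongest regions of replicate 1 alone and 56.5% with those of replicate 2 alone. Exons outside these windows held 15 summits (1.94%), against 28.2% of the other regions (odds ratio 0.0505, adjusted exact p = 2.63e-84), and the exon odds ratio was 0.102 with the strongest regions of replicate 2 alone and 0.0725 with those of replicate 1 alone. Introns held 171 (22.2% against 28.6%, odds ratio 0.711, adjusted exact p = 9.66e-05). Intergenic sequence held 177 (22.9% against 19.9%, odds ratio 1.20, adjusted exact p = 0.0448). The 2 last differences were small in the main comparison. Of the 171 intron summits, 70 were near a tRNA gene. Once regions within 300 bp of a tRNA gene were left out, the intron odds ratio was 0.483 (adjusted exact p = 1.62e-12). The intergenic one was then 1.05 (adjusted exact p = 0.612). With the strongest regions of replicate 2 in place of the optimal list the intergenic odds ratio was 0.902 (adjusted exact p = 0.273), and with those of replicate 1 the intron odds ratio was 0.867 (adjusted exact p = 0.104). The location tests were two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 4 classes. Over all pairs of a promoter summit and a gene whose window held it, the summit was a median of 264 bp upstream of the 5′ end (quartiles 152 and 474 bp). Of the 409 promoter regions, 150 lay in the windows of at least 2 genes and so entered this median more than once. Signal values inside and outside promoters did not differ past the threshold. The mean log2 signal value was 6.72 ± 0.57 (SD, n = 409) in promoters and 6.79 ± 0.64 (SD, n = 363) elsewhere (difference −0.07, permutation test, p = 0.0961). With a window of 500 bp upstream to 100 bp downstream, the difference was −0.13 and passed the threshold (permutation test, p = 0.00282).

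Among the classes of noncoding gene, tRNA and snoRNA genes had the largest odds ratios. Of the 772 summits, 147 (19%, 95% Wilson interval 16.4 to 22%) lay within 300 bp of a tRNA gene, against 0.852% of the other pooled regions (odds ratio 27.4, 95% limits 22 to 34.1, adjusted exact p = 4.55e-130). The tRNA odds ratio ranged from 15.9, with only regions found in both replicates as background, to 39.1 in the stronger 386 optimal regions. Small nucleolar RNA (snoRNA) genes, whose products guide the modification of ribosomal RNA, were within 300 bp of 61 summits (7.90% against 0.421%, odds ratio 20.3, adjusted exact p = 4.68e-50; from 9.61 within 1000 bp to 36.8 in the stronger 386). Small nuclear RNA (snRNA) genes lay beside 11 summits (1.42% against 0.137%, odds ratio 10.5, adjusted exact p = 9.96e-08) and microRNA genes beside 9 (1.17% against 0.305%, odds ratio 3.86, adjusted p = 0.00135). The microRNA difference rested on few regions and was not past the threshold with the strongest regions of replicate 2 alone (odds ratio 1.62, adjusted exact p = 0.321). Genes of other noncoding RNAs were near 232 summits (30.1% against 9.65%, odds ratio 4.02, adjusted exact p = 6.09e-54). Of these 232, 122 (52.6%) were also near a tRNA, snoRNA or snRNA gene, so the class overlaps those classes in part. Without tRNA neighbours the odds ratio was 2.71 (21.6% of optimal regions, adjusted exact p = 1.6e-19), smaller but still past the threshold. Pseudogenes were near 12 summits (1.55% against 2.42%, adjusted exact p = 0.176). No optimal summit lay near a ribosomal RNA gene (0 of 772, which allows a share of up to 0.495%, 95% Wilson limit), and only 1 of the other 29228 pooled regions did. These were two-sided Fisher's exact tests, adjusted over the 7 classes. Regions beside tRNA genes were also stronger than the rest, with a median signal value of 115 against 91.0 (difference of mean log2 values 0.16, permutation test, p = 0.00382).

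Counted by gene, 162 of 612 nuclear tRNA genes (26.5%, interval 23.1 to 30.1%) had an optimal summit within 300 bp, and in 95 of them a summit lay inside the tRNA gene itself. The strongest was WBGene00000308, a leucine tRNA gene on chromosome X at 13665555 to 13665673, with a summit at 13665566 inside the gene (signal value 358). Of the 346 snoRNA genes, 62 (17.9%, interval 14.2 to 22.3%) had an optimal summit within 300 bp, but only 3 had one inside the gene. The strongest was the pair *C51F7.3* and *C51F7.4* on chromosome V, beside a summit at 12303637 in an intron of *frm-7* (signal value 519). *ZK994.7*, in an intron of *pxn-1* on chromosome V, lay beside a summit at 8500571 (signal value 425). The 9 snRNA genes with an optimal summit, of 129, included *sls-2.1*, *sls-2.2*, *sls-2.4* and *sls-2.9*, genes of SL2 spliced leader RNAs. These noncoding genes were chosen for naming after their values were seen. Of the 171 optimal summits in introns, 99 (57.9%) were within 300 bp of a tRNA, snoRNA or snRNA gene, and 64 of the 177 intergenic ones (36.2%) were. In promoters 53 of 409 (13.0%) were. Promoter windows and these 3 kinds of gene accounted for 574 of the 772 optimal regions (74.4%).

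**Figure D3:**
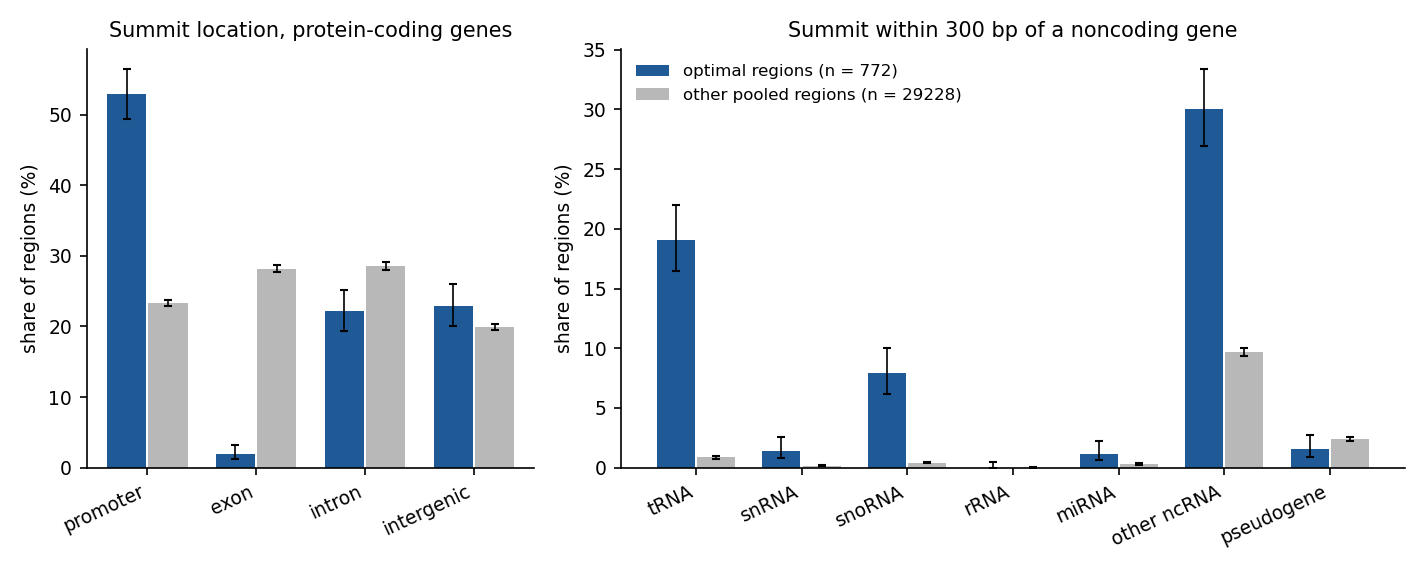
Share of optimal regions (blue) and of the other pooled regions (grey) by summit location (left) and within 300 bp of each class of noncoding gene (right). Bars are percentages of regions with 95% Wilson intervals. Promoters hold 53% against 23.3% and tRNA genes lie beside 19% against 0.852%.

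Promoters of ribosomal protein genes, and less stably those of chaperone and translation factor genes, carried optimal regions more often than other promoters. Of the 73 ribosomal protein genes among the 7127 genes with any pooled summit in the promoter window, 25 had an optimal summit there (34.2%, against 7.61% of other genes, odds ratio 6.32, 95% limits 3.87 to 10.3, adjusted exact p = 2.97e-09). The highest were *rpl-3* (signal value 294, summit 276 bp upstream), *rpl-35* (211, 454 bp upstream), *rpl-15* (196, 350 bp upstream) and *rps-20* (192, 230 bp upstream). Of 36 chaperone genes 10 had an optimal summit (27.8%, odds ratio 4.56, adjusted exact p = 0.00499), led by *dnj-29* (signal value 136), *hsp-60* (127), the mitochondrial chaperonin, and *cct-8* (126) and *cct-7* (124), subunits of the cytosolic chaperonin. Of 31 translation factor genes 8 had one (25.8%, odds ratio 4.11, adjusted exact p = 0.0220): the highest were *eef-1A.1* (signal value 146) and *eif-3.C* (146), followed by *iff-2* (124) and *eef-2*. No gene of these 3 lists had its optimal summit within 300 bp of a tRNA gene, and 2 ribosomal protein genes (*rps-12* and *rps-26*) had it within 300 bp of a snoRNA gene. Some summits lie in the windows of neighbouring genes and count for both, as for *eef-1A.1* and *rfc-4*. This also occurs within a list, as for *rpl-39* and *rps-30*, and the tests treat such genes as independent. These 3 of 30 tested lists passed the threshold (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Across settings the number ranged from 1 to 10, and the odds ratio of ribosomal proteins from 3.91 to 16.1. With the strongest regions of either replicate alone 6 lists passed, but beyond these 3 the lists differed. Replicate 2 added oxidative phosphorylation, splicing and, with a lower share, chemoreceptors, while replicate 1 added histones, cell cycle and DNA replication, and chromatin regulators. The 10 lists against all protein-coding genes included chemoreceptors and F-box and MATH-BTB genes with lower shares. With only pooled regions found in both replicates as background, or with each summit given to the nearest 5′ end, only the ribosomal protein list passed: the adjusted exact p of chaperones was then 0.124 and 0.143 and that of translation factors 0.164 and 0.0542.

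The other 27 lists missed the threshold. Those with the lowest adjusted p values were histones (7 of 32 genes, adjusted exact p = 0.0811), oxidative phosphorylation (9 of 52), cell cycle and DNA replication (11 of 70) and chromatin regulators (10 of 58), each of the last 3 with an adjusted p of 0.0997. Histone genes occur in near-identical copies, so the placement of reads among them is uncertain. Some also shared a summit, *his-67* with *his-68* and *his-61* with *his-62*. Germline genes had 5 of 28, splicing 6 of 46, vacuolar ATPase 2 of 15 and the mitochondrial ribosome 5 of 48. Aminoacyl-tRNA synthetases had 1 of 18 and the proteasome 1 of 25. Among lists of differentiated tissues, neurons had 4 of 45, body wall muscle 0 of 31, epidermis 0 of 26, pharynx 0 of 13 and intestine 0 of 11, and none of these differed past the threshold. The counts of 0 still allow shares of up to 11.0% (muscle), 12.9% (epidermis), 22.8% (pharynx) and 25.9% (intestine; 95% Wilson limits). Collagens had 2 of 57, neuropeptides 2 of 40, chemoreceptors 6 of 129, C-type lectins 2 of 54, F-box and MATH-BTB genes 4 of 109 and detoxification genes 1 of 30. Among lists of developmental regulators, the counts were homeodomain factors 1 of 38, nuclear hormone receptors 5 of 82, other developmental transcription factors 3 of 68 and Wnt and Notch signalling 1 of 31. The other MADF family genes had 0 of 8, and dosage compensation and sex determination genes 0 of 10. No list was lower past the threshold in this comparison.

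**Figure D4:**
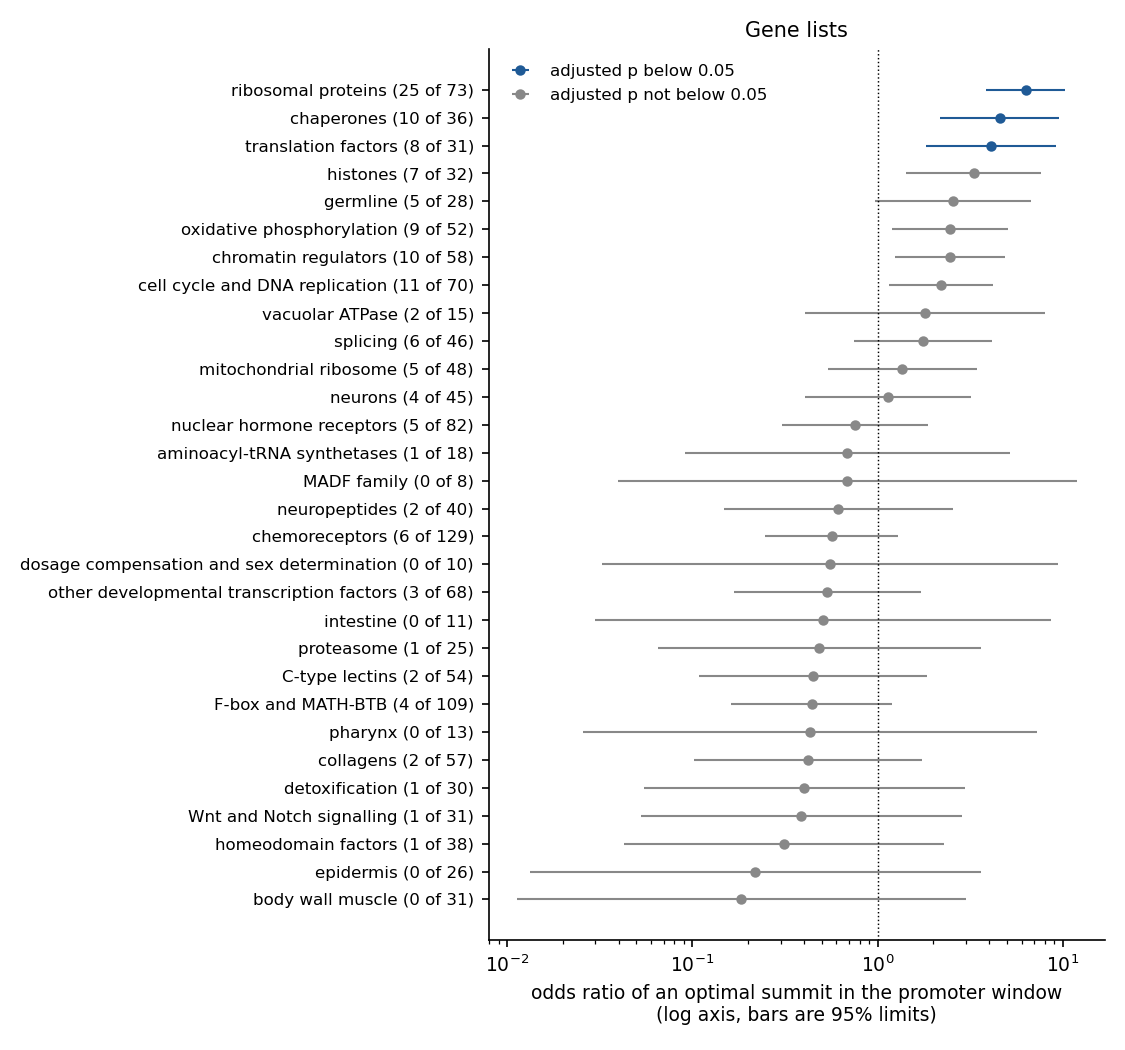
Odds ratio (log axis) of an optimal summit in the promoter window for each of the 30 gene lists tested, with 95% limits (0.5 was added to each cell of the table where a count was 0). Numbers in parentheses are genes with an optimal summit of the genes with any pooled summit. Ribosomal proteins (6.32), chaperones (4.56) and translation factors (4.11) are the lists past the threshold.

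Further genes named by the strongest promoter regions were of many kinds. On chromosome III, *tasp-1*, a threonine protease, and *K01G5.10* shared a summit at 10759234 (signal value 324). The clathrin adaptor gene *dpy-23* on chromosome X had one 252 bp upstream (304). On chromosome IV, the glutamyl-tRNA synthetase gene *ears-2* and its divergent neighbour *uncp-18* shared a summit at 390506 (275), and on chromosome III, *atx-2*, the ataxin-2 homologue, and *ecps-1* shared one at 10461322 (275). *Y39E4B.6* (273), the kinase gene *mrck-1* (272) and *T13C5.6* (250) followed. At 3 further loci the summit was also near a small noncoding gene: *sre-23* (422) and *T02E1.2* (317) on chromosome I near a snoRNA gene, and *cpr-9* and *gcy-33* (243) on chromosome V near a tRNA gene.

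The X chromosome held more optimal regions than its share of the other regions, and did not once regions beside tRNA genes were left out. Of the 772 summits, 177 (22.9%, interval 20.1 to 26%) were on X, against 16.5% of the other pooled regions (odds ratio 1.5, 95% limits 1.27 to 1.78, two-sided Fisher's exact test, p = 6.29e-06). Without regions within 300 bp of a tRNA gene, the share was 107 of 625 (17.1%) against 16.3% (odds ratio 1.06, 95% limits 0.859 to 1.31, exact p = 0.584), an alternative added after the tRNA result was seen. X carries 276 of the 612 nuclear tRNA genes (45.1%). tRNA genes on X had an optimal summit in 28.3% of cases and those on autosomes in 25% (odds ratio 1.18, 95% limits 0.824 to 1.69, Fisher's exact test, p = 0.407). Chromosome V held fewer optimal regions (12.4% against 16.9%, odds ratio 0.696, adjusted exact p = 0.00227 over the 6 chromosomes; without tRNA neighbours 0.749, adjusted p = 0.0903). On the autosomes, 224 of 595 optimal summits (37.6%) lay in the central of 3 equal parts of the chromosome, where conserved genes are denser, against 27.8% of the other regions (odds ratio 1.57, 95% limits 1.32 to 1.85, exact p = 3.38e-07).

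**Figure D5:**
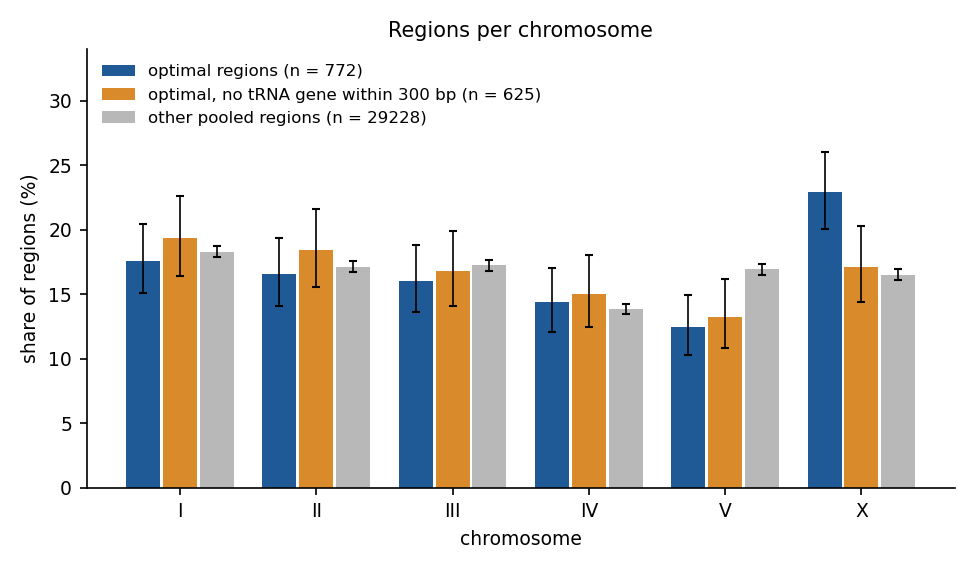
Share of regions on each chromosome for all optimal regions (blue), optimal regions with no tRNA gene within 300 bp (orange) and the other pooled regions (grey), with 95% Wilson intervals. On X the share is 22.9% for all optimal regions, 17.1% without tRNA neighbours and 16.5% for the other pooled regions.

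DNA at optimal summits was richer in G and C. The sequence window around a summit held 50.8% ± 6.87 GC (SD, n = 772 regions), against 43.0% ± 8.19 (SD, n = 29228), a difference of 7.76 percentage points (permutation test, p = 1e-05, the smallest that 100000 resamples can give). The difference was 4.81 points in the widest windows tried. The difference was 7.58 points in promoters, 11.3 in introns and 7.86 in intergenic sequence (permutation tests, adjusted p = 1.33e-05 each, from the smallest p that the resamples can give), and 0.980 in exons, where only 15 optimal summits lay (adjusted p = 0.611). Against 2316 windows matched on GC and promoter status, 221 of 2080 6-mers were more frequent and 230 less frequent at optimal summits (Fisher's exact tests, Benjamini-Hochberg adjusted). The leading 6-mer was CGCACA, in 15.5% of optimal windows against 5.22% (adjusted exact p = 1.18e-14). GTTCGA, which is part of the internal B box promoter of tRNA genes, was in 12.8% against 4.27% (adjusted exact p = 6.53e-12), and AACGCG in 13.7% against 4.92%. CCAGAA was in 1.42% against 7.34% and CTGGAA in 1.81% against 8.12%. The matched windows were not balanced for exons, which held 1.94% of all optimal summits against 28.2% of all other pooled regions. Part of the 6-mer differences, in either direction, may thus lie between exon and other sequence, which was not tested. Across settings the number more frequent ranged from 115 to 621, the latter against flanks of the same regions, which were not matched on GC or promoter status. The number of 6-mers less frequent ranged from 79 at the stricter threshold to 470 against flanks of the same regions. The leading 6-mer was not stable: CGCACA led again without regions near tRNA genes, where 140 were more frequent, but a different 6-mer led under every other setting (GAGAGA with the strongest regions of replicate 1 alone, ACGCGC with those of replicate 2 alone, or GTTCGA once mitochondrial regions were left out). CGCACA itself stayed more frequent at optimal summits under every 6-mer setting run, with ratios of shares from 2.28 to 6.32 (adjusted exact p at most 1.59e-06). The ratio of 6.32 was against the unmatched flanks, and the highest against matched windows was 3.51. Because the leading 6-mer changed, no single motif is named for the protein here. CpG dinucleotides numbered 7.21 ± 3.12 per optimal window (SD, n = 772) against 6.17 ± 2.99 in the matched windows (SD, n = 2316). The permutation test gave p = 1e-05, the smallest possible. For CpG too, the matched windows were not balanced for exons.

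The *madf-2* gene itself, on the minus strand of chromosome I at 11276448 to 11280018, held no region in any of the 4 ce11 lists. It lay in a gap of 56.4 kb without a pooled region, from 11254739 to 11311109. The control libraries were not analysed here, so the gap cannot be read as absence of binding.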

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

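Regions on mitochondrial DNA were listed for 1 replicate only, and read coverage was not examined. The list of replicate 2 held 14 regions on mitochondrial DNA, while that of replicate 1 and the pooled list held 0. The pooled list was called on both replicates, so 0 regions in a list need not mean no signal. These 14 regions covered 31.0% of the 13794 bp genome, had signal values from 82.3 to 832, and all 14 were among the 772 strongest of replicate 2, the highest of them at rank 1. The main comparisons use the pooled list and so hold none of them, but they enter the replicate overlap and the values for replicate 2 alone. Without them, an alternative added after they were seen, the overlap was 60.2% in place of 59.3% and the tRNA odds ratio of replicate 2 alone was 19.8 in place of 19.9. The noncoding classes past the threshold for replicate 2 alone went from 6 to 4, and its leading 6-mer from ACGCGC to GTTCGA. Chemoreceptors then no longer passed the threshold for replicate 2 alone, so 5 lists did in place of 6. The control libraries were not analysed here. No explanation was tested.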

How the results depend on the processing

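Over 260 values under alternative settings, 209 were kept, 21 moved, 16 passed the threshold anew, 12 fell short of it and 2 reversed. A tested value was kept if its direction and side of the threshold held. A count was kept if it stayed within a fixed ratio of the main count, and no error of a count was computed. So 163 and 295 6-mers more frequent, against 221 in the main setting, counted as kept. The promoter, tRNA and snoRNA excesses, the excess in autosome centres, the GC difference, the replicate overlap and the ribosomal protein list kept their calls under all alternatives run, but not their sizes. The odds ratio of ribosomal proteins ranged from 3.91 to 16.1, that of tRNA genes from 15.9 to 39.1, that of snoRNA genes from 9.61 to 36.8 and that of exons from 0.0471 to 0.102, and the GC difference from 4.81 to 8.95 points. The number of lists past the threshold was 5 at the stricter threshold, 6 with either replicate alone (6 to 6, of which only 3 lists are shared, and chemoreceptors in replicate 2 are lower), 5 with replicate 2 alone without its mitochondrial regions, 1 with regions present in both replicates as background, 7 with the window of 2000 bp upstream to 500 bp downstream, 10 with all protein-coding genes as background (chemoreceptors and F-box and MATH-BTB genes lower) and 1 with the nearest 5′ end. The number of 6-mers more frequent was 127 at the stricter threshold, 115 in 51 bp windows, 621 against flanks of the same regions (not matched on GC) and 140 without tRNA neighbours. The promoter difference in log2 signal was −0.13 with the window of 500 bp upstream to 100 bp downstream. The X odds ratio was 1.06 without tRNA neighbours. Replicate rho was 0.353 for 50% reciprocal overlap and 0.437 for summits within 100 bp. The intergenic odds ratio reversed to 0.902 without replicate 1 (range without a replicate 0.902 to 1.43), and to 0.938 when mitochondrial regions were left out too. The stricter threshold and the setting without tRNA neighbours left 386 and 625 optimal regions, fewer for each test. Whether having fewer regions moved any value was not tested, nor was the cause under the other settings. No paired analysis was possible because there is 1 group. Read depth is unknown, so the limits it sets cannot be given.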

Other observations

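The tests of the X share of the pooled list, of the gap around *madf-2*, of single against several tRNA copies, of tRNA products and of soft-masked sequence were chosen only after the result was seen. The test of shared tRNA reads, the ribosomal protein test, the X test without tRNA neighbours and both GC tests were written down before their own results. The X and GC tests without tRNA neighbours were nonetheless added after the data were seen. Several of the strongest regions lay outside promoters and near no tRNA, snoRNA or snRNA gene. The region of rank 5 (signal value 568) was intergenic on chromosome I at 933368 to 933667, 4.97 kb from the nearest protein-coding 5′ end, that of *nas-30*. The region of rank 7 (542) lay in an intron of *T18D3.9* on chromosome X at 12452071 to 12452574, and that of rank 14 (390) in an intron of *myrf-2* on chromosome X at 10188527 to 10188882. The region of rank 17 (348) was in an exon of *F22D3.4* on chromosome II at 6926068 to 6926375, 1 of only 15 optimal summits in exons. In all, 198 optimal regions (25.6%) were neither in a promoter window nor within 300 bp of a tRNA, snoRNA or snRNA gene. Some of these were near a gene of the other noncoding RNAs. Those that were not numbered 12 in exons, 50 in introns and 86 in intergenic sequence.

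tRNA genes of nearly all amino acids were among those with an optimal summit. The share was highest for alanine (14 of 34 genes, 41.2%) and cysteine (5 of 13, 38.5%) and lowest, apart from the single selenocysteine gene without one, for glutamine (4 of 27, 14.8%) and histidine (3 of 20, 15%). No product differed from the others after adjustment (Fisher's exact tests, lowest unadjusted p = 0.0701 for alanine, adjusted p = 1). The microRNA genes within 300 bp of an optimal summit were led by *cel-mir-51* (signal value 278) and *cel-mir-52* (187), both on chromosome IV and both of the mir-51 family. Soft-masked (repeat) sequence made up more than 50% of the window at 8.42% of optimal summits, against 17.3% of the other pooled regions (odds ratio 0.439, 95% limits 0.340 to 0.567, Fisher's exact test, p = 2.91e-12).

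The tRNA genes at the strongest regions may reflect binding, or may come from how reads were placed or which chromatin is recovered. Reads shared between tRNA genes of identical sequence are argued against as the whole source. Of 140 tRNA genes whose sequence occurs once in the genome, 24 (17.1%, interval 11.8 to 24.2%) had an optimal summit. These 24 were 34.3% of the 70 such genes with any pooled summit, while 2.57% of pooled regions are optimal. The first share counts genes and the second regions, so the comparison is approximate. For 20 of the 24 genes the summit had no tRNA gene of several copies within 300 bp. Near-identical genes count as single copies here, so reads shared between them were not tested. Genes of several copies had an optimal summit more often (138 of 472, 29.2%; odds ratio of single copies 0.501, Fisher's exact test, p = 0.00444), so a part played by shared reads stays open. Recovery of strongly transcribed genes whatever the antibody also stays open, since ribosomal protein promoters, transcribed by another polymerase, were in excess too (odds ratio 6.32). No biological explanation was tested, as the design has no untagged or mutant group.

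The X excess is consistent with the concentration of tRNA genes on X: without their neighbours the odds ratio was 1.06, with 95% limits of 0.859 and 1.31. The test of a higher X share of all candidate regions was void and decides nothing, because the excess is already measured against the other pooled regions. The pooled list held 16.7% on X and X makes up 17.7% of the nuclear genome length, a difference of −1.0 percentage points.

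The higher GC content may in part be a bias of the libraries. Among background regions in exons, where promoter and tRNA sequence play no part, signal rose with GC (Spearman rho 0.139 over 8234 regions), and rho was 0.238 in promoters, 0.258 in introns and 0.221 in intergenic sequence. tRNA sequence as the source is argued against, because the GC difference was 7.59 points without tRNA neighbours and 7.76 with them. A preference of the protein for such sequence stays open and was not tested. The main 6-mer comparison held GC fixed and so does not bear on this. The comparison with flanks did not hold GC fixed and cannot decide it.

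The gap in the pooled list around *madf-2* was among the longest: 46 of 26961 gaps between pooled regions were longer, and the median gap was 1.55 kb. The gap was 52.5 kb in the list of replicate 1 and 52.1 kb in that of replicate 2. It holds 21 annotated protein-coding genes. Extra copies of the stretch in the transgene may raise its coverage in the control and so leave no region to be called (gap of 56.4 kb in the pooled list). Coverage of the control libraries was not analysed here, and the extent and copy number of the transgene are not given in the sources used here, so what the gap means stays open.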
